A study of Mus musculus with 18 samples.

How the data were processed

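The samples were mouse bone marrow-derived macrophages, HET or KO for Wbp7, untreated or given LPS for 2 h or 4 h, measured on 18 Affymetrix gene arrays with 3 in each of 6 groups. The deposited values are log2 expression per probe set, made by the authors with RMA (background correction, quantile normalization and probe summarization over the arrays) in Partek 6.5. The settings, and whether probe sets had been left out, are not given in the sources used here. The values were tested for their scale, spread and equality between arrays before use and were analysed as deposited, with no further scaling. No column was left unused. As these are arrays, there is no count or depth per sample, and the number of arrays limits the precision; the median signal per array lay between 8.05 and 8.13.

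Of 25344 probe sets, 22667 had a gene in the platform's table, and 1530 of these were assigned to several genes and left out, as were the 2677 with none. The 21137 probe sets with a single gene gave 19475 genes. For the 915 genes with several probe sets, the probe set with the highest mean over the 18 arrays was used. The platform's symbols were kept. For 84 of the probe sets with a single gene, that gene was not in the RefSeq table. Genomic coordinates are not given here, since no genome build is given in the sources used here.

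One linear model with a mean for each of the 6 groups was fitted to all genes with limma 3.58.1 in R 4.3.3, with 12 residual degrees of freedom and the empirical Bayes step (prior degrees of freedom 3.17, prior SD 0.144). The contrasts were KO minus HET in untreated cells and at 2 h and 4 h, the LPS response at 2 h and 4 h in each genotype, the difference between genotypes in that response, and 4 h against 2 h in each genotype. The responses at 2 h and 4 h share their untreated arrays, so genes called at both are not counted as overlap. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the genes of its contrast. Overlaps between the LPS responses of HET and KO were set against the product of their shares of the genes tested. The size of the LPS response was measured over genes called for the average response of both genotypes with at least a 2-fold change, and compared per culture with an exact permutation test (two-sided). Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. The model was tested on simulated data: with 3 arrays per group it recovered 38% of changes of 0.5 log2 units and 90% of changes of 1 between genotypes in untreated cells, and 14% and 66% for the difference in the response at 2 h. The simulated noise was independent between arrays, with no shared cultures and no array standing apart. These rates therefore need not hold for the real arrays.

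The lists of genes, 21 in all, were written from textbook knowledge before the data were examined, as were the contrasts, the threshold, the rule for naming genes and the alternatives, unless stated otherwise. They cover GPI anchor biosynthesis, GPI-anchored proteins, immediate and late LPS response genes, the type I interferon response, TLR4 signalling, H3K4 methyltransferase complexes, macrophage identity, cell cycle, cholesterol synthesis and uptake, ER stress, glycolysis and hypoxia, p53 targets, antigen presentation and dendritic cells. Others hold markers of neutrophils, lymphocytes, erythroid cells, stromal cells and mast cells, the genes flanking Wbp7, and sex-linked genes. Each list was tested against all other genes with camera at a preset correlation of 0.01, with p adjusted over the 21 lists, and again with the correlation estimated from the data. Member genes were also adjusted over the list alone.

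Genes were named by rule: Wbp7, Pigp and Cd14 always; the 12 highest and 12 lowest changes among called genes whose arrays did not overlap between the groups (10 and 10 for an LPS response, and no condition on overlap for the difference in response); up to 4 called and 2 other members of each list; and every called member of the GPI biosynthesis list. With 3 arrays against 3, chance gives no overlap for 10% of genes. Where fewer than 5 genes were called, the 5 with the smallest p were given as values. Of the genes that the rule names, 1 is not reported here.

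The alternatives were arrays centred on their medians, quantile normalization, genes below the 40th percentile of mean signal left out (dim genes), the mean of a gene's probe sets, an intensity trend with a robust prior, array quality weights, a fit of the arrays of the contrast alone, a 2-fold minimum, and each array left out in turn. Replicate number was also used as a block over all arrays and within genotype (duplicateCorrelation, 0.398). Arrays of the same number and genotype deviated together from their group means (r across genes 0.32 to 0.80 in 18 pairs), and those of the same number in the other genotype did not as a rule (−0.353 to 0.39), so that the number was read as a culture within genotype. The labels do not state it. Some arrays that differed in both number and genotype also deviated together. HET replicate 3 and KO replicate 2 gave r = 0.574 untreated, 0.319 at 2 h and 0.561 at 4 h. A batch shared between genotypes is thus not excluded, and no fit here blocked on such pairs. A pair of alternatives was chosen after seeing the data: HET replicate 1 left out at all 3 times, and each culture as a fixed block for the lists. A value was counted as turned round only where it or its alternative passed the threshold. Where an array was left out, limma pooled the spread over all groups. The splits of the arrays were counted in full where there were 10; for the difference in response, 100 were used, the real one included and the others drawn with seed 7, exchanging single arrays within each time, and the 10 splits of whole cultures were counted apart. Probe sets that are further ones of a gene, have several genes or have none were fitted apart, over all probe sets, and are given in the closing section.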

Results

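Gene expression was measured on Affymetrix gene arrays in macrophages grown from mouse bone marrow and taken on day 7 of differentiation. The donor mice, of a mixed C57BL/6 and 129/Ola background, were heterozygous (HET) or homozygous (KO) for the loss of Wbp7, a gene also named Kmt2b, which encodes a methyltransferase for lysine 4 of histone H3. Cells of each genotype were left untreated or were given 10 ug/ml lipopolysaccharide (LPS), a bacterial product sensed through the receptor Tlr4, for 2 h or 4 h. This gave 6 groups of 3 arrays. The median signal per array lay between 8.05 and 8.13 on the log2 scale, and 19475 genes were tested. Changes below are log2 differences with the standard error (SE) of the limma fit and n = 3 arrays per group. A gene is said to have passed, risen or fallen where its Benjamini-Hochberg adjusted p over all genes was under 0.05. The number of arrays limits the precision of every value.

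The HET arrays numbered replicate 1 stood apart at all 3 times. Over all genes, the SD of their difference from another array of their group was 0.42 to 0.51, against 0.18 to 0.27 for the other pairs. Their cell cycle genes lay far lower: the median of the list was −2.89 (untreated), −2.76 (2 h) and −2.09 (4 h) below the mean of the other HET arrays, and 29 of its 36 measured members were over 1 log2 unit lower at all 3 times. In all, 267 genes were over 1 log2 unit lower and 39 over 1 log2 unit higher in these arrays at all 3 times. The higher ones included H2-Aa, H2-Ab1, H2-Eb1, Cd74 and Cd86, 5 of the 16 measured genes for antigen presentation. The interferon response list had a median 0.67, 0.61 and 0.22 higher in them. Each main count below was also taken without these 3 arrays, a choice made after they were seen to stand apart.

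Wbp7 itself did not pass on its probe set (10562005): KO minus HET was −0.24 untreated (SE 0.156, adjusted p = 1), −0.06 at 2 h (adjusted p = 0.915) and −0.09 at 4 h (adjusted p = 0.718). The untreated means were 10.66 ± 0.27 in HET and 10.41 ± 0.0627 in KO (SD, n = 3). Which part of the transcript this probe set covers is not given in the sources used here. Pigp (10441055), a subunit of the enzyme that starts the synthesis of glycosylphosphatidylinositol (GPI) anchors, was lower in KO at every time, by −0.56 untreated (SE 0.0947, adjusted p = 0.0147), −0.38 at 2 h (adjusted p = 0.0441) and −0.50 at 4 h (adjusted p = 0.0115). A further probe set assigned to Pigp (10545528), fitted among all probe sets, differed far more: −4.16, −4.04 and −3.49 (SE 0.359). In untreated cells its means were 9.27 ± 0.257 in HET and 5.12 ± 0.467 in KO (SD, n = 3). Its KO values (4.06 to 5.65) lay below the lower quartile of signal of every array, so the size of this difference is uncertain. Cd14, the GPI-anchored co-receptor for LPS, showed −0.11 (adjusted p = 1), −0.26 (adjusted p = 0.53) and −0.07 (adjusted p = 0.8). The Pigp result on the used probe set did not pass without untreated HET replicate 3, KO replicate 1 or KO replicate 3. At 2 h it did not pass without HET replicate 1 or 3 or any KO array, nor at 4 h without HET replicate 1 or KO replicate 2.

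**Figure D1:**
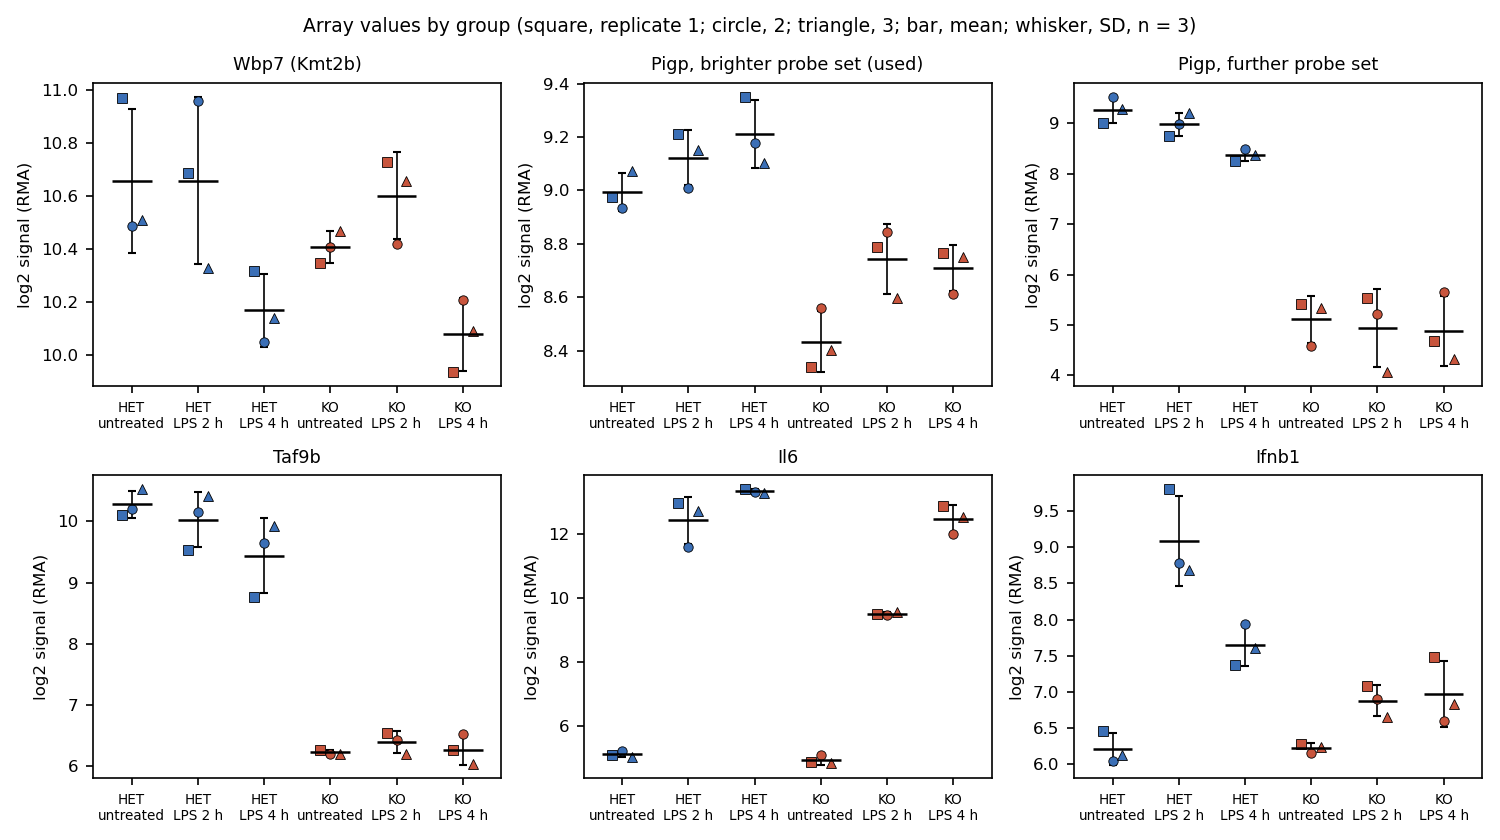
Signal on the log2 scale (vertical axis) of Wbp7, both Pigp probe sets, Taf9b, Il6 and Ifnb1 in each of the 18 arrays, by genotype and time (horizontal axis); horizontal lines are group means, whiskers 1 SD, and squares, circles and triangles replicates 1, 2 and 3. The further Pigp probe set and Taf9b were lower in every KO array than in every HET array, while Wbp7 overlapped between the genotypes at 2 h and 4 h.

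The comparison of untreated KO with untreated HET cells asked which genes differed before any stimulus. The KO genotype went mostly with lower expression: 70 genes were lower and 11 higher in KO. Taf9b, a relative of a general transcription factor subunit, stood at 6.22 ± 0.0393 in KO against 10.28 ± 0.22 in HET (SD), a difference of −4.06 (SE 0.257, adjusted p = 1.57e-06). Its highest KO array at any time (6.548) lay below the lower quartile of signal of every array, so the size of its difference is uncertain. Also lower were Stau2, an RNA-binding protein, by −2.70 (SE 0.258), Maged1 by −2.63 (SE 0.24) and Tlr3, the receptor for double-stranded RNA, by −1.41 (SE 0.206, adjusted p = 0.00453). The highest were Akr1c12, an aldo-keto reductase, by 1.90 (SE 0.275), Pla2g5, a secreted phospholipase, by 1.73 (SE 0.24), Mcoln3 by 1.59 (SE 0.305) and Chil3, a marker of alternative macrophage activation, by 1.46 (SE 0.284, adjusted p = 0.0338).

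Genes of the type I interferon response were lower as a group in untreated KO cells, with a median of −0.81 over 44 measured members, 42 of them below 0. Over all genes 1 of them passed, Tlr3; adjusted over the list alone, 33 passed, all lower. The camera test gave an adjusted p of 4.79e-41, and the adjusted p = 0.266 with an estimated correlation. Ifit3 at −1.81 (adjusted p = 0.314) and Ifi205 at −1.77 (adjusted p = 0.446) were examples that did not pass over all genes. Without HET replicate 1 the median was −0.55. The GPI biosynthesis list had 2 of 33 members lower, Pigp and the mannosyltransferase Pigz (−0.74, SE 0.0978, adjusted p = 0.0021), the same 2 when adjusted over the list alone, and no shift as a list (camera adjusted p = 0.769; its median, 0.03, and mean, −0.03, differ in sign). Cell cycle genes had a median of 0.835 with no member passing over all genes or over the list alone (camera adjusted p = 1.04e-06; adjusted p = 0.991 with an estimated correlation), and without HET replicate 1 this median turned to −0.13. The list was then called in the opposite direction with its 3 arrays left out (adjusted p = 1.09e-09), but not with the untreated one alone left out (0.415). Bub1 and Mki67, at 1.33 and 1.26, were at −0.04 and −0.09 without that replicate. Markers of neutrophils and their progenitors had a median of 0.02, with 1 of 19 members higher (camera adjusted p = 0.0186; adjusted p = 0.864 with an estimated correlation). That call ended without HET replicate 3 (0.273), KO replicate 1 (0.0788) or KO replicate 2 (0.209), and the median was negative without either KO array; quantile normalization gave 0.0778.

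The other lists gave no camera call in untreated cells. The adjusted p was 0.143 for the immediate and the late LPS response genes, for GPI-anchored proteins, for ER stress and for antigen presentation, 0.293 for p53 targets, 0.284 for lymphocyte markers, 0.593 for TLR4 signalling and for H3K4 methyltransferase complexes, and 0.612 for glycolysis. It was 0.616 for macrophage identity and for sex-linked genes, 0.744 for mast cell markers, 0.937 for erythroid markers and for the genes flanking Wbp7, 0.988 for stromal markers and 0.991 for cholesterol synthesis. Lymphocyte markers had 1 member higher when adjusted over the list alone. H2-Aa and H2-Ab1, which were high in HET replicate 1, showed −1.17 and −1.13 (adjusted p = 1 for both).

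Of the 25 genes that passed and were named by rule, 11 kept the call whichever array was left out (among them Akr1c12, Pla2g5, Gtsf1, Taf9b, Stau2, Maged1, Ttc3, Nipa1, Tlr3 and Pigz). The others lost it without at least 1. The total of 81 genes fell to 48 or 40 without HET replicate 2 or 3 and to 45, 41 or 25 without KO replicate 1, 2 or 3. It was 48 after quantile normalization, 50 with dim genes left out, 189 with array weights, 20 with only its 6 arrays fitted and 34 at 2-fold or more; without HET replicate 1 it was 118, with 69 of the 81 shared.

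After 2 h of LPS, the comparison of KO with HET asked how the genotypes differed early in the response. KO cells had much less of the cytokine transcripts Il6, at −2.94 (SE 0.268, adjusted p = 5.31e-05), and Ifnb1, the main early type I interferon, at −2.21 (SE 0.267, adjusted p = 0.00073). They also had less of the chemokine Cxcl9 (−2.77, SE 0.587, adjusted p = 0.0222) and the interferon-induced GTPase Iigp1 (−3.37, SE 0.524, adjusted p = 0.00427). Lower as well were endothelin Edn1 (−2.14, SE 0.413), Il27 (−1.93, adjusted p = 0.0128) and Tlr3 (−2.37, SE 0.206, adjusted p = 4.4e-05). Taf9b stood at −3.64 (adjusted p = 7.3e-06). Higher in KO were the transcription factors Fos (1.42, SE 0.262, adjusted p = 0.0116) and Myc (1.32, adjusted p = 0.04), the stress gene Sesn1 (2.11, SE 0.469, adjusted p = 0.0276) and again Akr1c12 and Pla2g5 (1.74 and 1.36). In all, 237 genes were higher and 300 lower in KO, shares that moved to 122 and 325 with each array centred on its median and to 145 and 289 after quantile normalization.

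The interferon list had 25 of 44 members lower at 2 h, 41 when adjusted over the list alone, and a median of −1.13 (camera adjusted p = 4.83e-40; adjusted p = 0.142 with an estimated correlation). Without HET replicate 1, whose interferon list lay 0.61 higher, 15 members passed and the median was −0.98. Late LPS response genes had 8 of 37 lower, among them Il6, Edn1, Il27 and the complement factor Cfb (−1.85, adjusted p = 0.0296). Adjusted over the list alone, 13 passed, and the list median was −0.98 (camera adjusted p = 3.8e-15; adjusted p = 0.0859 with an estimated correlation). Without HET replicate 1 that median was −0.59, with 6 passing. Immediate LPS response genes had 3 of 43 lower, Il1a (−1.19, SE 0.25, adjusted p = 0.0208), the chemokine Ccl4 (−0.72) and the NF-kB subunit Rel (−0.37), and 1 higher, Fos. Adjusted over the list alone, 10 were lower and 2 higher, with a median of −0.38 (camera adjusted p = 1.79e-09; adjusted p = 0.428 with an estimated correlation); without HET replicate 1 the median was −0.21.

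Among the other lists at 2 h, H3K4 methyltransferase complexes had a median of 0.28, with no member of 20 passing over all genes and 3 higher over the list alone. The call held at the preset correlation alone (camera adjusted p = 0.000251; adjusted p = 0.428 with an estimated correlation; median 0.14 without HET replicate 1). Cholesterol synthesis had 1 of 20 higher, Mvd (0.53, SE 0.126, adjusted p = 0.0353), also when adjusted over the list alone, and a median of 0.25 (camera adjusted p = 0.00243, and 0.0506 with dim genes left out; adjusted p = 0.568 with an estimated correlation). The GPI biosynthesis list had Pigz and Pigp lower and Pigh higher (0.44, adjusted p = 0.0467), with 4 lower and 1 higher over the list alone (camera adjusted p = 0.437). Cell cycle genes had a median of 0.99 with none passing (camera adjusted p = 0.000251; adjusted p = 0.737 with an estimated correlation), and 0.03 without HET replicate 1 (adjusted p = 0.863). GPI-anchored proteins had a median of −0.11 with none passing and a camera adjusted p of 0.0431 (adjusted p = 0.574 with an estimated correlation). It rose past the threshold without HET replicate 1 (0.101), 2 (0.0542) or 3 (0.051) or KO replicate 2 (0.185), after centring (0.0667) or quantile normalization (0.0639), with the mean of a gene's probe sets (0.0559), and without HET replicate 1 at all 3 times (0.052). Antigen presentation genes, higher in HET replicate 1, had a median of −0.24 (camera adjusted p = 0.0604, and 0.0395 with replicate number as a block).

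Of the 40 named genes that passed at 2 h, 12 kept the call whichever array was left out (Akr1c12, Pla2g5, Fam78a, Gtsf1, Taf9b, Iigp1, Ifi208, Il6, AA467197, Fmnl2, Tlr3 and Ifnb1). The others lost it without at least 1. The total of 537 genes was 147, 960 or 338 without HET replicate 1, 2 or 3 and 157, 167 or 237 without KO replicate 1, 2 or 3. It was 31 with only its 6 arrays fitted, 890 with replicate number as a block, 853 with array weights and 168 at 2-fold or more; without HET replicate 1 at all 3 times it was 417, with 302 shared.

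After 4 h of LPS, Il6 and Ifnb1 no longer passed, at −0.86 (SE 0.268, adjusted p = 0.1) and −0.67 (SE 0.267, adjusted p = 0.185), and other genes led. Lower in KO were the zinc transporter Slc30a4 (−3.31), Taf9b (−3.17, adjusted p = 1.26e-05), the G protein subunit Gnb4 (−2.91, SE 0.217, adjusted p = 7.93e-06), tissue factor F3 (−2.72), the collagen-modifying enzyme Plod2 (−2.60), Stau2 (−2.44) and Tlr3 (−1.38, SE 0.206, adjusted p = 0.00287). Higher were Sesn1 (2.36, SE 0.469, adjusted p = 0.0153), Akr1c12 (2.01), the chemokine receptor Cx3cr1 (1.85, adjusted p = 0.0301), Myc (1.47, adjusted p = 0.0268) and Gclc, an enzyme of glutathione synthesis (1.37). Cx3cr1 did not pass without HET replicate 1 (adjusted p = 0.0743). In all, 257 genes were higher and 215 lower.

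Cholesterol synthesis and uptake genes were higher in KO at 4 h: 4 of 20 passed, Msmo1 (1.01, SE 0.233, adjusted p = 0.0344), Fdft1 (0.93, SE 0.171, adjusted p = 0.0101), Stard4 (0.80, adjusted p = 0.0442) and Mvd (0.59, adjusted p = 0.0234). Adjusted over the list alone, 8 passed, and the median was 0.33 (camera adjusted p = 3.68e-06; adjusted p = 0.362 with an estimated correlation). Stard4 did not pass without HET replicate 1 (adjusted p = 0.0541). ER stress genes had 1 of 26 higher, Herpud1 (0.99, adjusted p = 0.0173), alone also over the list, and a median of 0.17 (camera adjusted p = 0.000509, and 0.0512 with dim genes left out; adjusted p = 0.362 with an estimated correlation). Late LPS response genes had none passing over all genes, 9 lower over the list alone, and a median of −0.39 (camera adjusted p = 0.00103; adjusted p = 0.598 with an estimated correlation). The interferon list had 1 member lower, Tlr3, also over the list alone, and a median of −0.33 (camera adjusted p = 0.000663; adjusted p = 0.744 with an estimated correlation), or −0.23 without HET replicate 1, where it lay 0.22 higher.

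H3K4 methyltransferase complexes had a median of 0.27 at 4 h with none passing (camera adjusted p = 0.000509; adjusted p = 0.577 with an estimated correlation; median 0.14 without HET replicate 1). Cell cycle genes had a median of 0.97 with none passing (camera adjusted p = 0.000185; adjusted p = 0.744 with an estimated correlation). Without HET replicate 1 that median was 0.175, with an adjusted p of 0.374 where only its 4 h array was left out and 3.15e-06 where all 3 were. Immediate LPS response genes had a median of −0.29 with none passing (camera adjusted p = 0.0138; adjusted p = 0.744 with an estimated correlation), and the call ended without HET replicate 2 (0.101) or KO replicate 2 (0.105). For p53 targets 1 of 18 was higher, 5 over the list alone, with a median of 0.13 (camera adjusted p = 0.0359; adjusted p = 0.362 with an estimated correlation). That call ended without HET replicate 3 (0.0873) or KO replicate 1 (0.0739), after quantile normalization (0.0715) and with dim genes left out (0.291). The GPI biosynthesis list had Pigz and Pigp lower, with 5 lower and 1 higher over the list alone (camera adjusted p = 0.281), and 1 GPI-anchored protein, Prnp, was lower (−0.83, adjusted p = 0.0397).

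Of the 37 named genes that passed at 4 h, 13 kept the call whichever array was left out (Akr1c12, Gtsf1, Pla2g5, Taf9b, Gnb4, Fmnl2, Plod2, Maged1, Dcbld2, Stau2, Zdhhc2, Ube2e2 and Tlr3). The others lost it without at least 1. The total of 472 genes was 189 without HET replicate 1 and 101 or 189 without KO replicate 2 or 3. It was 42 with only its 6 arrays fitted, 120 at 2-fold or more, 1274 with replicate number as a block, 1252 with array weights and 881 without HET replicate 1 at all 3 times, with 412 shared.

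Many genes were called at more than 1 time. The 3 times used separate arrays, but arrays of the same number and genotype deviated together, so that the times are not independent and no chance expectation is given. Lower in KO at all 3 times were 33 genes, among them Taf9b, Stau2, Maged1, Ttc3, Fmnl2, Tlr3, Pigp and Pigz. Higher at all 3 were 7: Akr1c12, Akr1c18, Gtsf1, Mcoln3, Pla2g2e, Pla2g5 and Sez6l2. Between 2 h and 4 h, 60 higher and 88 lower genes were shared. At 1 time or more, 434 genes were higher and 449 lower.

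In HET cells, 2 h of LPS raised the inflammatory genes Il1a by 7.35 (SE 0.25, adjusted p = 1.7e-10), Il6 by 7.32 (SE 0.268), Il1b by 5.97, Il12b by 5.57 and the chemokine Cxcl2 by 5.29, with Nos2, the inducible nitric oxide synthase, at 5.09. The phosphatase Dusp6 fell by 3.84 (SE 0.444, adjusted p = 2.55e-05) and the receptor Lpar6 fell by 3.32. In KO cells the same genes responded: Il1a rose by 6.38 (SE 0.25, adjusted p = 6.93e-10), Cxcl2 by 5.76, Il1b by 5.75, Il12b by 4.70 and Il6 by 4.57 (SE 0.268, adjusted p = 3.26e-08), and Dusp6 fell by 2.71. Cd14 rose in both, by 1.12 in HET (adjusted p = 0.00024) and 0.97 in KO (adjusted p = 0.00247), and Tlr4 fell in both, by −1.21 and −1.12. In HET 1083 genes rose and 1950 fell, and in KO 390 rose and 262 fell. Without HET replicate 1 at all 3 times, more genes fell than rose in KO (936 and 692). With each contrast fitted on its own arrays, KO had more calls than HET, so the order of these totals depends on the fit. Of the KO genes, 373 of 390 also rose in HET (21.7 expected by chance) and 251 of 262 also fell (26.2 expected).

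Immediate LPS response genes rose in 36 of 43 and fell in 2 in HET at 2 h, with a median of 2.06 (camera adjusted p = 2.06e-40, and 0.0216 with an estimated correlation). In KO 30 rose and 1 fell, with a median of 1.86 (1.76e-61, and 0.00423). Adjusted over the list alone, these were 37 and 2 in HET and 36 and 2 in KO. Late response genes rose in 29 of 37 in HET (median 2.64, camera adjusted p = 7.64e-27, and 0.0102 with an estimated correlation). In KO 17 rose (median 1.65, 1.37e-30, and 0.00423). Over the list alone these were 32 and 27. Interferon genes rose in 32 of 44 in HET (median 1.5, camera adjusted p = 1.26e-30; adjusted p = 0.192 with an estimated correlation). In KO 24 rose (median 1.12, camera adjusted p = 3.32e-37; adjusted p = 0.118 with an estimated correlation). Over the list alone these were 40 and 35. TLR4 signalling genes had 13 of 35 higher and 2 lower in HET (median 0.14, camera adjusted p = 0.0102; adjusted p = 0.329 with an estimated correlation). In KO 7 were higher and 1 lower (median 0.11, camera adjusted p = 0.0055; adjusted p = 0.227 with an estimated correlation), a call that ended without LPS replicate 3 (0.0643).

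In HET at 2 h, H3K4 methyltransferase complexes fell in 5 of 20 (median −0.27, camera adjusted p = 0.00099; adjusted p = 0.434 with an estimated correlation). Cholesterol genes fell in 2 of 20, 7 over the list alone (camera adjusted p = 0.00539, 0.0999 with dim genes left out, 0.0729 without untreated replicate 1 and 0.0815 without all 3 of its arrays; adjusted p = 0.48 with an estimated correlation). GPI biosynthesis genes fell in 3 of 33 and rose in 1, the mannosyltransferase Pigv, by 1.42 (camera adjusted p = 0.0492; adjusted p = 0.47 with an estimated correlation). That call ended without the 2 h replicate 1 (0.429), untreated replicate 2 (0.0688) or 3 (0.193). It also ended after quantile normalization (0.415), with dim genes left out (0.342) and without HET replicate 1 at all 3 times (0.0964). With each culture as a fixed block, a choice made after the data were seen, cell cycle genes were lower at 2 h in HET (median −0.46, adjusted p = 5.22e-07, against 0.104 without the block) and KO (−0.21, adjusted p = 1.1e-05, against 0.0833). Antigen presentation genes were then higher in HET (0.00113, against 0.0585) and KO (0.000139, against 0.0735). So were markers of other cell types: stromal markers in HET (0.00255, against 0.0843) and KO (0.0221, against 0.118), and neutrophil markers in HET (0.00126, against 0.0247). At 4 h this block also gave calls, all higher, for antigen presentation (0.00695, against 0.0785) and neutrophil markers (0.00824, against 0.0725) in HET. In KO it gave them for GPI-anchored proteins (0.0327, against 0.07), glycolysis (0.0194, against 0.17) and neutrophil markers (0.0102, against 0.0705).

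For the response at 2 h, 47 of 66 named genes in HET and 30 of 39 in KO kept the call whichever array was left out; the others lost it without at least 1. The HET total of 3033 genes fell to 1900 without the 2 h replicate 1, and the KO total of 652 to 416, 417 or 412 without the 2 h replicate 1 or 3 or untreated replicate 3. Blocking on culture within genotype gave 4979 in HET and 1422 in KO, fitting only the arrays compared 1115 and 1604, and a 2-fold minimum 782 and 279. The KO total was 2237 with array weights and 1628 without HET replicate 1. HET arrays enter the KO total only through the spread pooled over all groups and its degrees of freedom.

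By 4 h more genes had changed in both genotypes. In HET Il6 had risen by 8.23 (SE 0.268, adjusted p = 5.06e-11), Il1a by 7.60, Nos2 by 6.62 and Edn1 by 5.95, while the stress gene Sesn1 fell by 3.98 and the phosphodiesterase Pde3b fell by 3.38. In KO Il6 had risen by 7.55 (SE 0.268, adjusted p = 1.08e-10), Il1a by 7.42, Il1b by 6.48 and Nos2 by 5.92, while the glycosyltransferase Gcnt1 fell by 2.59 and the receptor S1pr1 fell by 2.49. Ifnb1 in KO was at 0.75 and did not pass (adjusted p = 0.0723). In HET 3057 genes rose and 4028 fell. In KO 1262 rose and 1807 fell, of which 1182 (198 expected) and 1703 (374 expected) did the same in HET. The order of the HET and KO totals turned round with each contrast fitted on its own arrays. With arrays centred on their medians, the median over all genes of the HET response at 4 h was 0.114, against 0.0852 as deposited and 0.00399 after quantile normalization.

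At 4 h immediate response genes rose in 37 of 43 in HET (median 1.82, camera adjusted p = 1.94e-22; adjusted p = 0.144 with an estimated correlation). In KO 36 rose and 1 fell (median 1.98, camera adjusted p = 5.73e-37, and 0.0305 with an estimated correlation). Late genes rose in 31 of 37 in HET (median 3.29, camera adjusted p = 5.99e-17; adjusted p = 0.0604 with an estimated correlation), and 26 did so in KO (median 2.76, camera adjusted p = 9.15e-27, and 0.0103 with an estimated correlation). Interferon genes rose in 43 of 44 in HET (median 1.97, camera adjusted p = 5.35e-23; adjusted p = 0.261 with an estimated correlation). In KO 42 rose (median 2.69, camera adjusted p = 1.95e-49; adjusted p = 0.0518 with an estimated correlation). Cholesterol genes fell in 17 of 20 in HET, Msmo1 by −1.90 (SE 0.233, adjusted p = 1.6e-05) and Stard4 by −1.71. As a list they gave a shift there (median −0.91, camera adjusted p = 9.91e-08; adjusted p = 0.207 with an estimated correlation). In KO 6 fell, Msmo1 by −0.90 (adjusted p = 0.0142) and Stard4 by −0.93, and the list also gave a shift (median −0.43, camera adjusted p = 5.11e-05; adjusted p = 0.386 with an estimated correlation). H3K4 methyltransferase complexes fell in 15 of 20 in HET (median −0.49, camera adjusted p = 3.88e-05; adjusted p = 0.307 with an estimated correlation). In KO 7 fell (median −0.29, camera adjusted p = 0.000417; adjusted p = 0.386 with an estimated correlation). Adjusted over the list alone, 32 late genes rose in HET and 29 in KO, 43 interferon genes rose in each, and 15 methyltransferase complex genes fell in HET and 8 in KO.

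GPI biosynthesis genes at 4 h fell in 13 of 33 and rose in 4 in HET, Pigv by 1.54 and Pgap2 by 1.00 (median −0.29, camera adjusted p = 0.0169; adjusted p = 0.351 with an estimated correlation). That call ended without the 4 h replicate 1 (0.112), untreated replicate 3 (0.0525) or all 3 arrays of replicate 1 (0.0503), after quantile normalization (0.445) and with dim genes left out (0.293). In KO 5 fell and 2 rose (camera adjusted p = 0.0463; adjusted p = 0.5 with an estimated correlation). This was not called without the 4 h replicate 1 (0.11), untreated replicate 2 (0.0592) or 3 (0.0951), after quantile normalization (0.455) or with dim genes left out (0.331). Cell cycle genes fell in 4 of 36 in HET (median −1.03, camera adjusted p = 0.0166; adjusted p = 0.706 with an estimated correlation). The median was −0.04 without the 4 h replicate 1 (0.435), with no call without untreated replicate 2 (0.138) or 3 (0.169) or with dim genes left out (0.317). Leaving out the 4 h replicate 1 kept its untreated array, whose list was also low (8.79, against 11.54 and 11.56 in the other untreated HET arrays). In KO 3 fell (median −0.65, camera adjusted p = 0.0159, and 0.184 with dim genes left out, adjusted p = 0.747 with an estimated correlation). With each culture as a fixed block, a choice made after the data were seen, 31 cell cycle genes fell and 1 rose in HET (camera adjusted p = 3.35e-10). In KO 29 then fell and 0 rose (camera adjusted p = 9.31e-12). ER stress genes fell in 11 of 26 and rose in 1 in HET (camera adjusted p = 0.0211; adjusted p = 0.427 with an estimated correlation). This was not called without the 4 h replicate 1 (0.0839), untreated replicate 2 (0.07) or all 3 arrays of replicate 1 (0.127), or with dim genes left out (0.317). TLR4 signalling in KO had 11 higher and 2 lower (camera adjusted p = 0.0242, and 0.0718 without untreated replicate 1; adjusted p = 0.386 with an estimated correlation).

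For the response at 4 h, 75 of 97 named genes in HET and 47 of 69 in KO kept the call whichever array was left out; the others lost it without at least 1. The KO total of 3069 was 2026 without the 4 h replicate 1, 5073 with culture blocked within genotype, 5296 with array weights, 5387 without HET replicate 1 at all 3 times, 5002 with only its arrays fitted and 905 at 2-fold or more. The HET total of 7085 was 10450 with culture blocked, 3991 with only its arrays fitted and 1832 at 2-fold or more. With only its own arrays fitted, KO thus had more calls than HET (5002 against 3991).

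The comparison of 4 h with 2 h asked how the response moved on. In HET cells Ifnb1 fell by 1.44 (SE 0.267, adjusted p = 0.0033), the chemokine Cxcl1 fell by 1.74 (SE 0.272, adjusted p = 0.00107), and Cfb (1.91), Nos2 (1.52) and Il18 (1.34) rose further. In KO cells Il6 rose further, by 2.98 (SE 0.268, adjusted p = 7.14e-05), as did Iigp1 by 4.26 (SE 0.524, adjusted p = 0.000281), Cfb by 2.75, Cxcl9 by 2.48, Tlr3 by 2.44 and Nos2 by 2.39. Interferon genes rose in 30 of 44 in KO, 39 over the list alone (median 1.34, camera adjusted p = 1.2e-48; adjusted p = 0.0815 with an estimated correlation). In HET 5 rose and 1 fell, 12 and 1 over the list alone (median 0.56, camera adjusted p = 8.2e-07; adjusted p = 0.928 with an estimated correlation). Late response genes rose in 10 of 37 in KO (median 0.72, camera adjusted p = 1.68e-13; adjusted p = 0.0815 with an estimated correlation). In HET 6 rose (median 0.42, camera adjusted p = 0.00851, and 0.0515 without the 2 h replicate 2; adjusted p = 0.928 with an estimated correlation). Cholesterol genes fell in 10 of 20 in HET, Msmo1 by −1.19 (median −0.48, camera adjusted p = 1.2e-09; adjusted p = 0.292 with an estimated correlation). In KO 2 fell, Stard4 by −0.82 (median −0.42, camera adjusted p = 9.75e-07; adjusted p = 0.275 with an estimated correlation). In HET 740 genes rose and 854 fell. In KO 523 rose and 329 fell, or 571 and 218 with arrays centred. Without HET replicate 1 at all 3 times, 909 rose and 1497 fell in KO, so the more frequent direction there depends on the fit.

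H3K4 methyltransferase complexes had a median of −0.19 in KO at 4 h against 2 h, with none passing. The camera adjusted p was 0.00318, and the adjusted p = 0.65 with an estimated correlation. With culture as a fixed block, cell cycle genes were lower at 4 h than at 2 h in HET (median −0.53, adjusted p = 1.14e-09, against 0.0616) and in KO (−0.43, adjusted p = 3.05e-10, against 0.13). It also gave calls, all higher, for stromal markers in HET (0.00624, against 0.0959), and for GPI-anchored proteins (0.0212, against 0.0869) and glycolysis (0.00492, against 0.097) in KO. The HET total of 1594 was 2575 or 795 without the 2 h replicate 1 or 2, 1060 without its replicate 3, and 1017 without the 4 h replicate 1. It was 102 with only its arrays fitted, 3194 with culture blocked within genotype, 2500 with array weights, 339 at 2-fold or more and 2691 without HET replicate 1 at all 3 times. The KO total of 852 was 480 or 543 without the 2 h replicate 1 or 2, 454 or 441 without the 4 h replicate 1 or 3, and 1898 with culture blocked, 2973 with array weights, 2066 with only its arrays fitted, 268 at 2-fold or more, or 2406 without HET replicate 1. Of the named genes, 15 of 38 named genes in HET and 11 of 25 in KO kept the call whichever array was left out, and the others lost it without at least 1.

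Whether the LPS response itself differed between genotypes was tested as the KO response minus the HET response. At 4 h, 10 genes passed, 8 of them with a negative difference. These were Gnb4 (−2.08, adjusted p = 0.0294), the leukotriene receptor Cysltr2 (−1.51, adjusted p = 0.0205), the cytokine receptor Il23r (−1.45, adjusted p = 0.0423) and the Notch ligand Dll1 (−1.34, adjusted p = 0.0391). The others were Angpt1 (−1.31, adjusted p = 0.0217), Hap1 (−1.16, adjusted p = 0.0165), Slc37a3 (−0.91) and Tnks1bp1 (−0.81). The nucleolar protein Gnl3 (1.57, adjusted p = 0.0391) and Tbc1d12 (0.87) had a positive difference. Gnl3 fell with LPS on average over the genotypes (−1.698), so its positive value is a smaller fall in KO. At 2 h limma called 0 genes, with 1099 at an unadjusted p under 0.05; Il6 came nearest, at −2.75 (SE 0.38, adjusted p = 0.0523), and Ifnb1 was at −2.22 (SE 0.378, adjusted p = 0.115). With culture blocked within genotype, 35 genes passed at 2 h, Il6 (adjusted p = 0.00488) and Ifnb1 (adjusted p = 0.0109) among them, and 98 at 4 h. None of the 10 genes at 4 h kept the call whichever array was left out.

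By list, the KO response at 2 h was smaller for late LPS response genes (median difference −0.70, camera adjusted p = 1.32e-12; adjusted p = 0.145 with an estimated correlation). It was also smaller for immediate response genes (−0.29, camera adjusted p = 7.73e-07; adjusted p = 0.636 with an estimated correlation) and interferon genes (−0.22, camera adjusted p = 8.63e-08; adjusted p = 0.755 with an estimated correlation). Adjusted over the list alone, 6 late genes were lower, 1 immediate gene was lower and 1 higher, and 1 interferon gene was lower. Without HET replicate 1 these medians were −0.56, −0.28 and −0.27. At 4 h the late list was still lower (−0.265, camera adjusted p = 0.0426; adjusted p = 0.701 with an estimated correlation). That call ended without HET 4 h replicate 1 (0.053) or 2 (0.0766), KO 4 h replicate 2 (0.159), or untreated HET or KO replicate 2 (0.143 and 0.142), and after centring (0.0876) or quantile normalization (0.0779). The interferon list had turned to 0.42 (camera adjusted p = 2.04e-06; adjusted p = 0.701 with an estimated correlation), or 0.345 without HET replicate 1. Cholesterol genes had a positive difference at 2 h (0.335, camera adjusted p = 0.00202, adjusted p = 0.636 with an estimated correlation). They also had one at 4 h (0.41, camera adjusted p = 7.16e-07, adjusted p = 0.674 with an estimated correlation). This was a smaller fall in KO, with medians of −0.0608 against −0.301 in HET at 2 h, and −0.426 against −0.913 at 4 h. The call at 2 h ended without untreated HET replicate 1 (0.0579) or without all 3 of its arrays (0.17).

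H3K4 methyltransferase complexes had a positive difference at 2 h (0.20, camera adjusted p = 0.00202, adjusted p = 0.636 with an estimated correlation). They also had one at 4 h (0.24, camera adjusted p = 0.00416, adjusted p = 0.701 with an estimated correlation). Their medians fell less in KO: −0.109 against −0.269 in HET at 2 h, and −0.292 against −0.49 at 4 h. These calls ended without HET replicate 1 of 2 h (0.2) and of 4 h (0.138), and the call at 4 h also after quantile normalization (0.147) and with dim genes left out (0.0931). Neither ended with HET replicate 1 left out at all 3 times, or with culture as a fixed block (camera adjusted p = 0.00139 and 0.00414). The neutrophil list was lower at 2 h (−0.26, camera adjusted p = 0.00284; adjusted p = 0.589 with an estimated correlation), but not without the 2 h HET or KO replicate 2 (0.0547 and 0.0521). ER stress genes had a positive difference at 4 h (0.15, camera adjusted p = 0.0179, adjusted p = 0.701 with an estimated correlation), with medians of −0.0893 in KO and −0.221 in HET. This was not called without the 4 h HET replicate 1 (0.184) or untreated HET replicate 2 (0.116). Nor was this called after quantile normalization (0.0855), with dim genes left out (0.252) or without HET replicate 1 at all 3 times (0.308). With culture as a fixed block the cell cycle list, whose median fell less in KO, had a positive difference at 2 h (0.23, adjusted p = 0.0014, against 0.688) and 4 h (0.285, adjusted p = 0.000316, against 0.337). Without the block it was called in the opposite direction without the 2 h array of HET replicate 1 (−0.83, adjusted p = 1.62e-05) and without its 4 h array (−0.52, adjusted p = 0.0371). Both fits kept the untreated array of that replicate, whose list was also low, and so broke up the culture. With all 3 of its arrays left out there was no call in the opposite direction. With the same block, immediate response genes (−0.17, adjusted p = 0.0307, against 0.14) and stromal markers (−0.13, adjusted p = 0.00595, against 0.14) were called lower at 4 h. The 4 h total of 10 genes became 2, 1 or 0 without untreated HET replicate 1, 2 or 3, and 0, 2 or 2 without untreated KO replicate 1, 2 or 3. It became 4 without 4 h HET replicate 1, 4 without its replicate 2, and 6, 3 or 4 without 4 h KO replicate 1, 2 or 3. It was 5 with dim genes left out, 39 with array weights and 52 without HET replicate 1 at all 3 times. At 2 h limma called 40 without HET 2 h replicate 2, 1 without untreated HET replicate 1 and 8 with array weights.

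The size of the response was compared over genes that passed and changed by at least 2-fold on average over the genotypes. The 369 genes induced at 2 h rose by a median of 1.92 in HET and 1.31 in KO, and 322 of them (87.3%) rose less in KO. The 134 repressed genes fell by medians of −1.51 and −0.93, with a median difference of 0.64, or 0.402 with the genes chosen in KO alone. At 4 h the 719 induced genes had medians of 1.74 and 1.48, with 70.9% smaller in KO, and the 632 repressed genes −1.5 and −1.04, with 93.2% smaller. The median over the genes of each set was also taken within each culture. At 2 h its mean over the cultures was 1.93 ± 0.222 in HET and 1.33 ± 0.203 in KO for induced genes (SD, n = 3). For repressed genes it was −1.57 ± 0.318 and −0.95 ± 0.0467. At 4 h the means were 1.76 ± 0.114 and 1.48 ± 0.128 for induced genes and −1.54 ± 0.166 and −1.05 ± 0.1 for repressed genes. The exact permutation test (two-sided) gave p = 0.1 for each of the 4, the smallest this design allows. When the interaction was adjusted over the induced genes of 2 h alone, 19 passed as lower in KO, among them Il6 (adjusted p = 0.000991), Ifnb1 (adjusted p = 0.00363) and Nos2 (−1.56, adjusted p = 0.0269); of the repressed genes, 31 passed, Fos among them (1.62, adjusted p = 0.0101). At 4 h 15 induced and 18 repressed genes passed in this way; those genes had been chosen on the same arrays.

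Across these comparisons camera called 71 list results. With an estimated correlation 6 remained called: the immediate and the late response lists at 2 h in HET and KO and at 4 h in KO. The calls kept were 54 with dim genes left out, 58 after quantile normalization, 68 with arrays centred, 70 with the mean of a gene's probe sets and 61 without HET replicate 1, where 9 ended and 1, the cell cycle list in untreated cells, turned round. The calls not described above were small shifts, each of which ended without at least 1 array. They were stromal markers at 4 h in both genotypes, antigen presentation at 4 h in KO, neutrophil markers at 2 h in HET and for 4 h against 2 h in KO, immediate response genes for 4 h against 2 h in KO, and H3K4 and ER stress genes for 4 h against 2 h in HET.

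**Figure D2:**
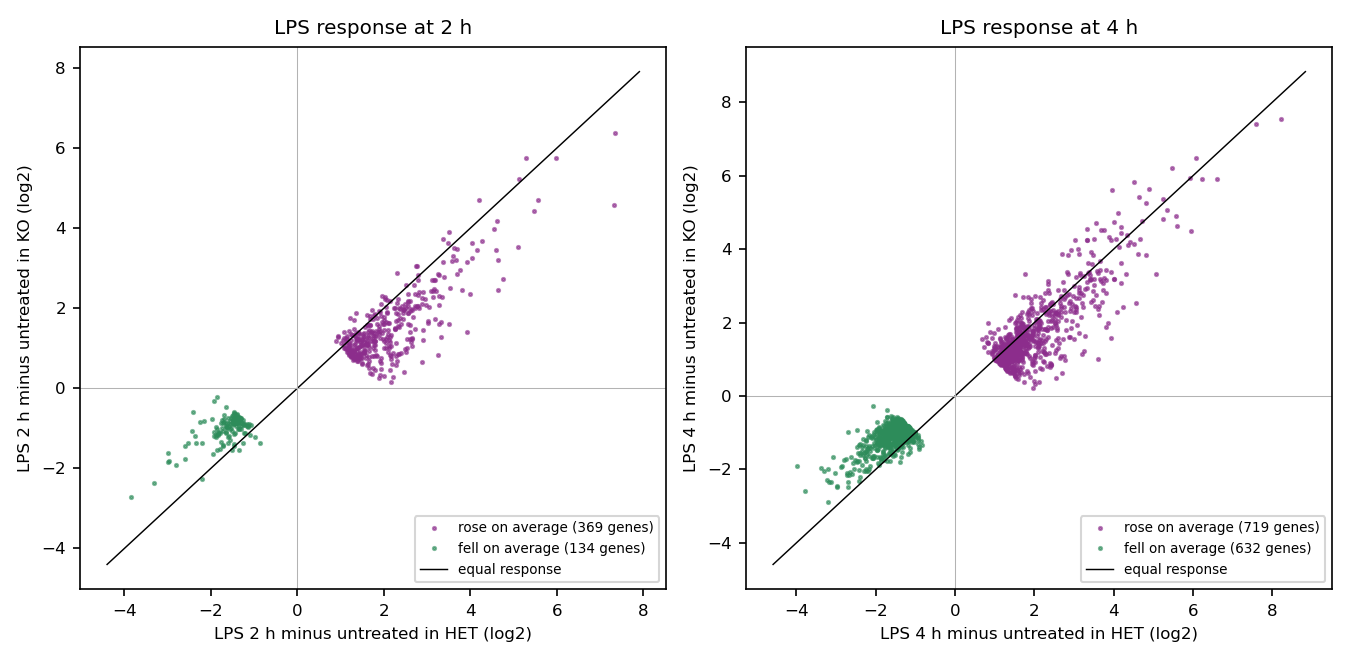
LPS response in KO (vertical axis, log2) against that in HET (horizontal axis, log2) at 2 h and 4 h; each point is a gene that rose or fell at least 2-fold on average over the genotypes, and the line marks an equal response. At 2 h, 322 of 369 induced genes lie below the line.

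**Figure D3:**
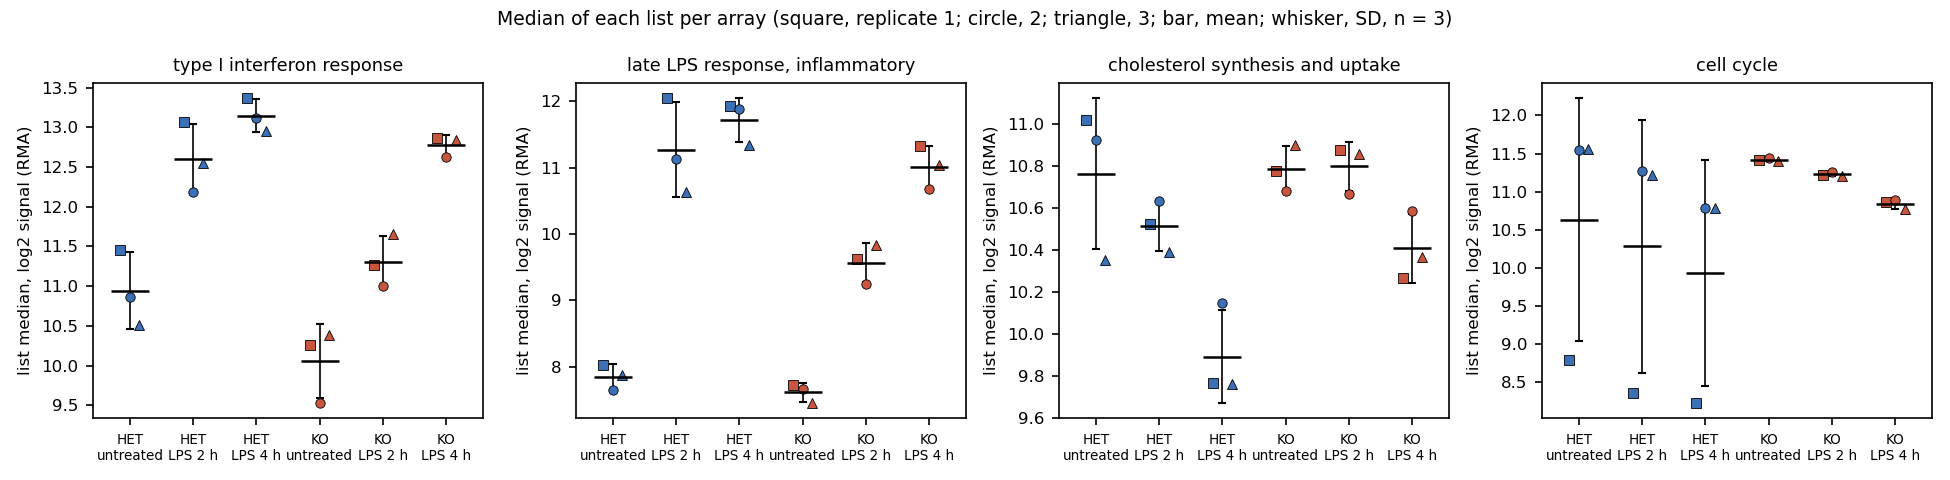
Median signal on the log2 scale (vertical axis) of the interferon, late LPS response, cholesterol and cell cycle lists in each of the 18 arrays, by genotype and time (horizontal axis), with squares, circles and triangles for replicates 1, 2 and 3. The HET arrays of replicate 1 lie lowest for the cell cycle list at all 3 times.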

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

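The tests on HET replicate 1, on its part and that of the normalization in the smaller KO response, and on chromosomes were chosen only after the result was seen; the others were planned.

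The LPS response differed between genotypes by a test of the difference itself for several lists and genes. At 2 h the median KO minus HET difference was −0.294 for immediate LPS response genes, −0.70 for late ones, −0.219 for the interferon response, 0.201 for H3K4 methyltransferase complexes, 0.335 for cholesterol synthesis and −0.263 for neutrophil markers. At 4 h it was −0.265 for late genes, 0.423 for interferon genes, 0.241 for H3K4 methyltransferase complexes, 0.407 for cholesterol synthesis and 0.147 for ER stress. None of these 11 list results passed with an estimated correlation. Some medians moved with 1 array. Without the 4 h array of HET replicate 1, those at 4 h were 0.129 for H3K4 methyltransferase complexes, 0.0624 for ER stress and −0.152 for late genes. The late list was at −0.37 without the 4 h array of HET replicate 2. Cholesterol synthesis at 2 h was at 0.191 without the untreated array of HET replicate 1. The genes with a different response at 4 h were Gnb4 (−2.077), Cysltr2 (−1.513), Il23r (−1.447), Dll1 (−1.337), Angpt1 (−1.314), Hap1 (−1.155), Slc37a3 (−0.9109), Tnks1bp1 (−0.8071), Tbc1d12 (0.8734) and Gnl3 (1.569).

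Probe sets outside the comparisons also differed between genotypes. Among further probe sets of a gene, 13 were called untreated, 42 at 2 h and 52 at 4 h. Among those assigned to several genes, limma called 0 untreated, 38 at 2 h and 32 at 4 h, and among those with no gene listed 3, 32 and 87. The further probe set of Pigp was lower in KO, at −4.157 untreated, −4.037 at 2 h and −3.488 at 4 h. As its KO values lay below the lower quartile of signal of every array, the size of this is uncertain.

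The first pattern is the set of genes called between genotypes. Sex of the donor animals is argued against, since the largest mean difference of Xist or a Y-linked gene was 0.174 log2 units. DNA of 129 origin around the targeted locus showed no excess of calls: 1 of 38 flanking genes was called at any time (2.63%), against 882 other genes (4.54%, Fisher's exact test, two-sided p = 1). The 38 genes are too few to make up the set, and too few for the test to exclude a modest excess. Another cell type mixed in cannot be told apart: none of 6 lists of other cell types had more than 1 called member in untreated cells, under the bound of 3 set beforehand, but a count of non-calls excludes little, and camera called the neutrophil list there (adjusted p = 0.0186; adjusted p = 0.864 with an estimated correlation), a call lost after quantile normalization (0.0778) and without untreated HET replicate 3 (0.273) or KO replicate 1 (0.0788) or 2 (0.209). An effect of the genotype the labels give, which the Wbp7 probe set itself does not show, stays open, as do a difference between the donor animals, not tested, and 129-derived DNA elsewhere. By chromosome, genes lower in KO at 2 h were in excess on 1 (30 of 300, Fisher's exact test, adjusted p = 0.0147) and 14 (21, 0.0185). They were fewer than their share on 7 (12, 0.0147) and 15 (2, 0.0147), while no chromosome passed untreated or at 4 h. Fisher's test takes genes as independent, so neighbouring genes that respond together could also give an excess. These counts therefore do not decide on 129-derived DNA.

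The second pattern is the smaller LPS response in KO. A large loss of receptor transcripts is argued against: untreated differences were 0.0088 for Tlr4 (SE 0.263), −0.112 for Cd14 (SE 0.167) and 0.12 for Ly96 (SE 0.178). None was lower by more than the bound set beforehand, but these SEs do not exclude a modest loss. The replicate 1 cultures of HET account for part at most, since at least 71.6% of each median difference was left without them, and a scaling difference left in the deposited values likewise, with at least 86.2% left after quantile normalization or centring; for repressed genes chosen in KO alone the difference was 0.402 at 2 h, against 0.64, and 0.357 at 4 h, against 0.51. The authors' own normalization was not rerun here and stays open, and protein at the cell surface was not analysed here. A weaker response in the KO genotype, which the Wbp7 probe set does not show as a loss, remains a hypothesis, since the exact permutation test on the medians per culture gave p = 0.1, the smallest that 3 cultures against 3 allow.

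The third pattern is that the HET replicate 1 arrays stood apart, with a low cell cycle list at all 3 times. A KO culture labelled HET is argued against, since these arrays lay at least 2.21 log2 units above the highest KO array in the further Pigp probe set and Taf9b. Both had drawn attention by their difference between the labelled genotypes, which limits the weight of this. A wild-type culture labelled HET is not addressed, as no wild-type array was at hand. The normalization is argued against: one that keeps the order of signals within an array moves genes of like signal alike, yet the cell cycle list lay −1.93 or further below the 200 genes nearest in signal at every time. Another cell type mixed in cannot be told apart from a change within the macrophages: at most 31.2% of a list of another type was over 1 log2 unit higher at all 3 times, in the antigen presentation list, whose genes activated macrophages also express. No biological explanation was tested, since the labels place no group there, and a culture that had stopped dividing earlier may be one.

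Other splits of the same arrays were fitted for each count. With 6 arrays the 10 splits are too few for a share under 0.05. Each other split also mixes arrays of the real groups, so a large difference between them, as with LPS, adds to the spread and lowers the count. A count of 0 in those splits therefore says little about chance. The real counts and the highest of the other splits were 81 and 5 for the untreated genotype difference, 537 and 0 at 2 h, 472 and 0 at 4 h, 3033 and 0 for LPS at 2 h in HET, 7085 and 0 at 4 h, 652 and 0 at 2 h in KO, 3069 and 0 at 4 h, and 852 and 0 for 4 h against 2 h in KO. For 4 h against 2 h in HET, 2 of the 10 splits gave as many genes: the real one with 1594, and one with 1722 that kept the replicate 1 arrays together with replicate 2 of 4 h. That points to a structure of the samples; blocking on culture gave 3194, and among the 4 splits that part all 3 numbers the highest other was 1. For the difference in response at 2 h the count of splits decides nothing: limma called 0 genes (1099 at an unadjusted p under 0.05), which all 100 splits, the real one included, must reach (highest other 513). At 4 h, 8 of 100 splits, the real one included, gave at least the 10 genes (highest other 317), so chance cannot be excluded by them. These splits exchange single arrays and break up the cultures, and their large counts point to a structure of the samples. Where whole cultures were moved, the 10 splits are too few for a share under 0.05; the highest other was 1 at 4 h.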

How the results depend on the processing

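The runs without HET replicate 1 at all 3 times and those with each culture as a fixed block were chosen only after the result was seen. All values are counts of called genes unless stated, and the cause of a change was not tested except where fewer genes or arrays or a stricter rule made it. Leaving out HET replicate 1 changes the counts within KO only through the spread pooled over all groups and its degrees of freedom. No direction of a named gene turned round where the value or its alternative passed the threshold. Where neither passed, some did, as with Bub1 and Mki67 in untreated cells without HET replicate 1. Of 3700 values for genes named between genotypes, 3271 kept their side of the threshold, 375 lost the call and 54 gained it. Of 2246 for the difference in response these were 2111, 105 and 30, and of 9295 for the LPS responses 8237, 536 and 522. Leaving out dim genes gave no value for the named genes it dropped.

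For the untreated genotype difference (81 genes) the count was 48 after quantile normalization, 50 with dim genes left out, 189 with array weights, 20 with only its 6 arrays fitted, 34 at 2-fold or more, and 25 to 58 with each array left out. At 2 h (537) it was 890 with the replicate block, 853 with array weights, 31 with only its arrays, 168 at 2-fold and 147 to 960 with each array left out. At 4 h (472) it was 1274 with the replicate block, 1252 with array weights, 881 without HET replicate 1, 42 with only its arrays, 120 at 2-fold and 101 to 665 with each array left out.

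For LPS at 2 h in HET (3033) the replicate block within genotype gave 4979, only its arrays 1115, a 2-fold minimum 782, and each array left out 1900 to 3123. At 4 h in HET (7085) only its arrays gave 3991 and a 2-fold minimum 1832. For LPS at 2 h in KO (652) the block within genotype gave 1422, array weights 2237, leaving out HET replicate 1 1628, only its arrays 1604, 2-fold 279, and each array left out 412 to 512. At 4 h in KO (3069) these were 5073, 5296, 5387, 5002, 905, and 2026 to 2667. For 4 h against 2 h in HET (1594) they were 3194, 2500, 2691, 102, 339, and 795 to 2575, and in KO (852) 1898, 2973, 2406, 2066, 268, and 441 to 800.

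For the difference in response at 2 h, where limma called 0 (1099 at an unadjusted p under 0.05), centring gave 1, quantile normalization 1, dim genes left out 2, the replicate block 2, the block within genotype 35, the trend with a robust prior 1, array weights 8, leaving out HET replicate 1 1, and each array left out 0 to 40. At 4 h (10) dim genes left out gave 5, the block within genotype 98, array weights 39, leaving out HET replicate 1 52, and each array left out 0 to 10.

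The median difference of the response size was 0.402 for genes that fell at 2 h and 0.357 at 4 h when the genes were chosen in KO alone, against 0.64 and 0.51. The cell cycle list turned round with HET replicate 1: untreated, its median of 0.835 became −0.128 without it (camera adjusted p = 1.09e-09 with its 3 arrays left out, 0.415 with the untreated one), with a range of −0.128 to 1.33 over the arrays left out; at 2 h the range was 0.0338 to 1.53, and for the difference in response −0.826 to 1.11 at 2 h and −0.516 to 1.09 at 4 h. The lowest values for the difference in response were calls in the opposite direction (camera adjusted p = 1.62e-05 and 0.0371), without the array of HET replicate 1 at 2 h and at 4 h. Those fits kept the untreated array of that replicate, whose list was also low, and so broke up the culture. What the arrays limit is precision: the median SE was 0.121 for a difference between groups and 0.171 for a difference in response.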

Other observations

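The test on the further Pigp probe set was chosen only after the result was seen; the gene lists were planned.

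LPS also moved genes of macrophage identity and of cell survival in both directions in both genotypes. At 2 h the myeloid transcription factor Cebpa fell by 1.25 in HET (SE 0.154, limma adjusted p = 4.6e-05) and fell by 0.88 in KO (SE 0.154, adjusted p = 0.00293), and the inhibitory Fc receptor Fcgr2b rose by 1.24 and 0.80. Of 33 measured genes of macrophage identity, 3 rose and 3 fell in HET and 3 rose and 2 fell in KO at 2 h, and camera gave no call (adjusted p = 0.413 and 0.265). At 4 h Cebpa stood at −1.67 in HET and −1.56 in KO.

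Among 18 p53 targets and apoptosis genes, the death receptor Fas rose at 2 h by 3.28 in HET (SE 0.216, adjusted p = 7.79e-08) and 2.82 in KO (SE 0.216, adjusted p = 8.13e-07). The pro-apoptotic Bcl2l11 rose by 1.69 and 1.39, and Trp53inp1 fell by 1.51 and fell by 1.08. The list had 2 higher and 5 lower in HET and 2 higher and 1 lower in KO, with no camera call (adjusted p = 0.582 and 0.832; its median and mean differ in sign in KO). Pfkfb3, a regulator of glycolysis, rose at 4 h by 3.08 in HET (SE 0.478, adjusted p = 0.000132) and 1.94 in KO (SE 0.478, adjusted p = 0.0105). None of these differences between the genotypes in the response was called.

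A hypothesis for the further Pigp probe set was that the probe set lies outside the Pigp locus and may measure another transcript. Probe sets near each other in number tend to lie on the same chromosome on this array. Of the 20 named probe sets nearest to it by number, 0 had a gene on the chromosome of Pigp, against 20 of 20 for the probe set used; over all named probe sets, neighbours by number shared a chromosome in 94.3% of cases. This is consistent with a locus elsewhere, so its large difference between the genotypes is not read here as one of Pigp itself. A retrotransposed copy or another gene could give such a signal, and neither was tested.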
